A study of Mus musculus with 8 samples.

How the data were processed

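RNA of sorted prostate epithelium from mice of 2 genotypes (PP and PPK), each as sham at 3.5 months and ADT at 6.5 months, was measured in 8 libraries, 2 per group. Per the labels, total RNA was extracted with Trizol and made into strand-specific TruSeq libraries. FPKM values, meaning fragments scaled for gene length and library size, were computed by the authors, and 1 table per library was deposited. The submitters' processing notes name FastQC 0.11.2 and the build mm10. The aligner, the quantifier and the annotation are not given in the sources used here. The organoid experiments that the design text mentions were not analysed here.

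The 8 tables were joined on 55335 Ensembl identifiers. Symbols and positions came from GENCODE M21 on GRCm38, which matched 55154 identifiers and left 181 without a symbol. No counts are in the tables, so depth is unknown and no counting interval is given. Of 15 housekeeping genes checked none was listed at 0 in any library. A gene listed at 0 in both libraries of a group gets no fold change between groups. The difference of effects is still given for Tcaf3, at 0 in all ADT libraries, as a fitted value that rests on the sham libraries. Groups were taken from the sample labels. The letters A and B mark replicates, and the labels do not say whether these are separate animals. Deviations of libraries with the same letter correlated at -0.008 to 0.057 between groups, so the letters were not used as pairs. FPKM cannot part reads among near-identical genes. This concerns Sbp and Sbpl, Scgb, Svs3a and Svs3b, haemoglobin, Lyz1 and Lyz2, Ifi202b, Krt6a and Krt6b, Sprr2a, Fabp5, Hspa1a, H2 and ribosomal protein genes.

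Genes with FPKM of at least 1 in at least 2 libraries were tested (14000). Log2(FPKM + 1) was fitted with limma 3.58.1 in R 4.3.3 as 4 group means with a mean-variance trend (4 residual and 2.4 prior degrees of freedom). The 5 comparisons were PPK against PP in sham and in ADT mice, ADT against sham in PP and in PPK, and the difference of both genotype effects. A gene passed with a Benjamini-Hochberg adjusted p under 0.05 from limma, two-sided. Joining, tables and plots used Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9. The 33 gene lists cover lineage, secretion, metabolism, stress, proliferation and immunity, and 9 lists of other cell types. They were written from general knowledge, and the 29 with at least 5 tested members were tested with camera of limma at a preset correlation between genes of 0.01, adjusted over the lists of a comparison. For each list the members that passed are counted over all genes tested and adjusted over the list alone. Members under the FPKM filter were not tested. This left 3 of 22 lymphocyte, 4 of 15 neutrophil and 4 of 13 endothelial genes. It left 7 of 18 neuroendocrine and 13 of 20 macrophage and monocyte genes. The calls that did not hold with an estimated correlation are given with that p.

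Groups, comparisons, tests, lists, the rule for named genes and all alternatives but 2 were chosen before the data were examined. The exceptions are limma treat against a 2-fold change and the left-out libraries for the agreement of effects. Named were Kmt2c, and the 8 genes with the largest change in each direction (6 for the difference of effects). These had to pass, have groups that do not overlap and a mean of at least 5 FPKM in the higher group. Predicted models and immunoglobulin or T cell receptor segments were left out. From each list up to 4 members with the smallest adjusted p could be named, or the 2 with the highest mean FPKM where none passed. Krt19 for ADT with age in PP and Itga6 and Epcam in ADT mice were named after their values were seen. Some genes that this rule names, and 1 list, are not reported here.

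The test was tried on simulated data, in 5 runs per comparison with 200 changed genes among 14000. It recovered 60.8 to 68.0% of 2-fold and 87.2 to 92.8% of 4-fold changes in the 4 pairwise comparisons, and 48.4 and 73.2% for the difference of effects. It called 0.028 to 0.043% of unchanged genes. With 200 changed genes the Benjamini-Hochberg cut is stricter than in the data, where 4000 to 8765 genes passed. These rates thus do not carry over to the data. A list raised by 0.5 was called in 5 of 5 runs of each comparison. Of 28 unchanged lists per run, 2 were called over the 5 runs of PPK against PP in sham mice and 0 in the other comparisons. The simulated noise was independent between genes. In the data the estimated correlation was 0.259 for ribosomal protein genes and 0.384 for mitochondrially encoded genes. The list rates thus do not carry over to lists whose members vary together. Alternatives changed 1 choice each: pseudocount 0.1, no filter, a mean FPKM of at least 5, median-of-ratios scaling, quantile normalization, a replicate block, only the 2 groups compared, no trend, array weights, a log2 fold change of at least 1, each library left out, and for lists an estimated correlation and fry.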

Results

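RNA from sorted mouse prostate epithelium (EpCAM+, CD24a+, CD49f-low cells, per the series' design text) was sequenced in 8 libraries that fall into 4 groups of 2. The labels give all mice 1 shared prostate genotype (PP), and PPK mice carried Kmt2cPC-/- as well. Each genotype was profiled in sham mice at 3.5 months and in ADT mice at 6.5 months of age. ADT is the usual abbreviation of androgen deprivation therapy, and the labels do not say how it was done. Treatment and age changed together, so every ADT difference below is a difference of ADT with age. The files list FPKM values for 55335 genes without counts, so the depth of each library is unknown. Summed FPKM ranged from 284015 in PP ADT replicate A to 333977 in PPK ADT replicate B. Levels are mean FPKM of n = 2 libraries per group, with SD where ± follows a level. Fold changes are log2 differences of FPKM + 1, which understate changes of low genes, with ± SE. In brackets after a gene stand its level in the first group named, vs that in the reference group, and its log2 fold change. For each fixed gene list the median is that of the log2 fold changes of its tested members.

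Kmt2c, the targeted histone methyltransferase gene (ENSMUSG00000038056, chromosome 5, 25271798 to 25498783, GRCm38), was read at 13.3 and 13.9 FPKM in PP sham and at 8.67 and 8.15 in PPK sham. It was read at 10.3 and 9.33 FPKM in PP ADT and at 6.60 and 6.36 in PPK ADT. The log2 fold change of Kmt2c in PPK against PP was -0.63 ± 0.066 in sham mice (limma adjusted p = 0.000795) and -0.53 ± 0.066 in ADT mice (limma adjusted p = 0.00054). Kmt2c was thus lower and not absent in the PPK libraries. It was also lower after ADT with age, with a log2 fold change of -0.43 ± 0.066 in PP (limma adjusted p = 0.00248) and -0.33 ± 0.066 in PPK (limma adjusted p = 0.00473). The labels do not give the deleted part, and a value over the whole gene also counts exons that remain.

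The 2 libraries of a group were nearly alike, with Pearson correlations across genes of 0.986 to 0.989 within groups and 0.805 to 0.958 between groups. The first principal component held 63.9% of the variance and placed the PPK ADT libraries at 79.5 and 79.8, against -41.8 to -4.04 for the other 6. The PP ADT libraries stood apart on the second component (19.9% of the variance), at 45.0 and 45.2.

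**Figure D1:**
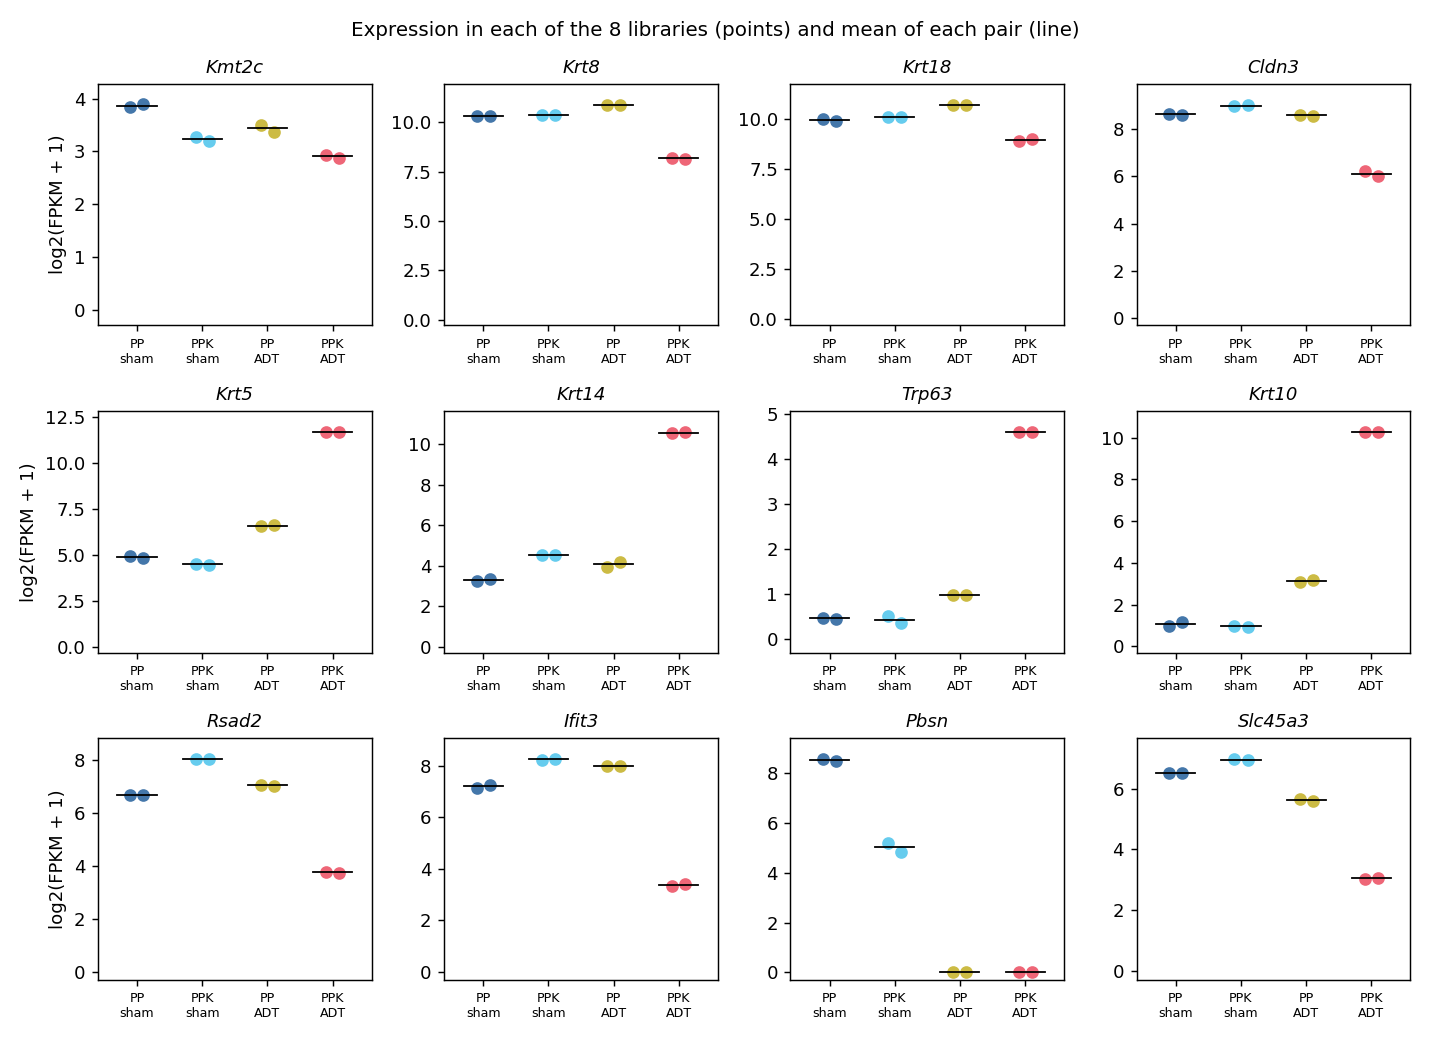
Level of 12 genes in each of the 8 libraries as log2(FPKM + 1) on the vertical axis, by group on the horizontal axis, with 1 point per library and a line at the mean of each pair. Krt5, Krt14, Trp63 and Krt10 stand highest and Krt8, Krt18, Cldn3, Rsad2 and Ifit3 lowest in the PPK ADT pair, and Pbsn is listed at 0 in all 4 ADT libraries.

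The first comparison asked how the prostate epithelium of sham mice differed between PPK and PP. In PPK sham, interferon-induced genes were higher than in PP sham: Bst2, which tethers budding virus, stood at 224 ± 1.51 against 69.0 ± 2.11 FPKM (SD, n = 2 each), a log2 fold change of 1.68 ± 0.031. Several secretory genes of the normal prostate were far lower. Tgm4, the prostate transglutaminase, stood at 0.895 ± 0.00544 against 66.6 ± 0.254 FPKM (-5.16 ± 0.079), and Pbsn, which encodes the secretory protein probasin, at 31.8 ± 5.74 against 366 ± 14.9 (-3.50 ± 0.11). Klk1, a kallikrein gene, went the other way, from 5.25 ± 0.706 to 189 ± 3.68 FPKM (4.93 ± 0.084, limma adjusted p = 1.5e-06). Genes of cholesterol and fatty acid synthesis were lower, and genes of the hypoxia response were higher.

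Of 14000 genes tested, 4000 differed, 1920 higher and 2080 lower in PPK sham, and 515 of them differed at least 2-fold (274 higher, 241 lower). Beside Klk1, large increases included Dmbt1 (49.6 vs 4.0, 3.34 ± 0.086), a mucosal scavenger glycoprotein, Slfn4 (53.6 vs 5.33, 3.11 ± 0.098), a Schlafen family gene, and Msln (46.5 vs 4.59, 3.09 ± 0.079), which encodes mesothelin. The androgen-binding protein genes Scgb1b20 (23.1 vs 0.773, 3.77 ± 0.13) and Scgb2b20 (28.2 vs 2.67, 2.99 ± 0.12) rose too, and Scgb1b3 was listed at 0 in both PP sham libraries and at 5.66 ± 0.690 FPKM in PPK sham. The mitochondrial transfer RNA gene mt-Tg also passed (2.75 ± 0.48), with 8.32 and 25.9 FPKM in the PPK sham pair. Other large decreases included Tcaf3 (0.919 vs 90.7, -5.58 ± 0.075), Rnase1 (2.78 vs 89.9, -4.59 ± 0.056), a secreted ribonuclease, Defb1 (7.26 vs 120.2, -3.89 ± 0.16), a beta-defensin, Upk1b (3.84 vs 61.9, -3.70 ± 0.072), a uroplakin of urothelium, Sult1c2 (0.602 vs 18.3, -3.60 ± 0.10) and Fam25c (3.08 vs 40.5, -3.35 ± 0.10).

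Among interferon response genes, 19 of 24 tested members rose and 5 did not pass (21 higher adjusted over the list alone), median 0.76, camera adjusted p = 1.64e-14. Examples were Rsad2 (259 vs 101, 1.35 ± 0.028), which encodes the antiviral protein viperin, Isg15 (339 vs 156, 1.12 ± 0.029) and Ifit3 (301 vs 146, 1.04 ± 0.042). Genes of antigen presentation moved with them: 13 of 15 tested members rose and 2 did not pass (14 higher adjusted over the list alone), median 0.75, camera adjusted p = 2.92e-08. These included the class I heavy chain genes H2-D1 (1543 vs 853, 0.86 ± 0.027) and H2-K1 (975 vs 589, 0.73 ± 0.023), and Nlrc5 (11.8 vs 4.64, 1.18 ± 0.056), a transactivator of class I genes. Markers of macrophages and monocytes were higher as well: 11 of 13 tested members rose and 2 fell (11 higher and 2 lower adjusted over the list alone), median 0.82, camera adjusted p = 0.000362, adjusted p = 0.0568 with an estimated correlation. Examples were Cd14 (90.5 vs 41.5, 1.11 ± 0.079) and Cd68 (21.1 vs 11.3, 0.84 ± 0.067). Fibroblast markers rose beside them, as 10 of 13 tested members rose and 3 did not pass (11 higher adjusted over the list alone), median 0.75, camera adjusted p = 5.10e-08. The collagen genes Col1a1 (5.44 vs 0.866, 1.79 ± 0.098) and Col3a1 (4.14 vs 0.562, 1.72 ± 0.091) stayed low in level, whereas C3 (72.8 vs 13.9, 2.31 ± 0.029), a complement gene also made by epithelium, was abundant. In the smooth muscle list, 5 of 6 tested members rose and 1 fell (5 higher and 1 lower adjusted over the list alone), median 0.55, camera adjusted p = 0.00375, adjusted p = 0.087 with an estimated correlation. Its most abundant gene was Tpm2 (26.8 vs 5.75, 2.04 ± 0.046). All 4 tested neutrophil markers, of 15 listed, rose (4 higher adjusted over the list alone), among them Lcn2 (174 vs 61.0, 1.5 ± 0.067) and Ltf (204 vs 100.1, 1.02 ± 0.034), which secretory epithelium also makes. Only 2 of the 4 reached a mean of 1 FPKM in PP sham, so the others may have been tested only because another group was high. In the list of epithelial-mesenchymal transition, 11 of 13 tested members rose, 1 fell and 1 did not pass (11 higher and 1 lower adjusted over the list alone), median 0.89, camera adjusted p = 2.00e-05, adjusted p = 0.0855 with an estimated correlation. Examples were Fn1 (12.4 vs 5.13, 1.13 ± 0.050), the fibronectin gene, Sparc (9.45 vs 2.71, 1.49 ± 0.087) and Itga5 (6.42 vs 1.86, 1.38 ± 0.10).

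Cholesterol synthesis genes were lower: 16 of 23 tested members fell and 7 did not pass (18 lower adjusted over the list alone), median -0.39, camera adjusted p = 1.60e-06. Examples were Stard4 (5.07 vs 13.1, -1.22 ± 0.074), Hmgcs1 (20.3 vs 37.8, -0.87 ± 0.076), the HMG-CoA synthase gene, and Cyp51 (20.8 vs 31.9, -0.60 ± 0.054). In fatty acid synthesis and SREBP1 targets, 11 of 21 tested members fell and 10 did not pass (1 higher and 14 lower adjusted over the list alone), median -0.40, camera adjusted p = 0.00015. Examples were Acsl3 (19.5 vs 36.3, -0.86 ± 0.064) and Acly (30.4 vs 43.2, -0.49 ± 0.041), the ATP citrate lyase gene. Hypoxia and glycolysis genes were higher, since 15 of 22 tested members rose and 7 did not pass (15 higher adjusted over the list alone), median 0.26, camera adjusted p = 5.45e-07. Examples were Car9 (17.8 vs 3.71, 1.99 ± 0.11) and Pfkp (6.76 vs 2.57, 1.11 ± 0.099). In the unfolded protein response list, 1 of 20 tested members rose, 15 fell and 4 did not pass (1 higher and 16 lower adjusted over the list alone), median -0.31, camera adjusted p = 9.64e-07, adjusted p = 0.0768 with an estimated correlation. Examples were Hspa5 (273 vs 398, -0.54 ± 0.020), the main chaperone of the endoplasmic reticulum, and Herpud1 (53.9 vs 99.5, -0.87 ± 0.079). Immediate early genes, which tissue dissociation also induces, were lower beside it: 2 of 20 tested members rose, 16 fell and 2 did not pass (2 higher and 16 lower adjusted over the list alone), median -0.46, camera adjusted p = 1.89e-09. Examples were Fos (404 vs 847, -1.07 ± 0.035) and Ier2 (146 vs 274, -0.90 ± 0.030). Among Wnt and Notch targets, 7 of 13 tested members fell and 6 did not pass (7 lower adjusted over the list alone), median -0.28, camera adjusted p = 0.00444, adjusted p = 0.0855 with an estimated correlation. Examples were Hes1 (156 vs 205, -0.39 ± 0.033) and Nrarp (8.41 vs 13.5, -0.62 ± 0.070). In the senescence and SASP list, 10 of 21 tested members rose, 4 fell and 7 did not pass (11 higher and 5 lower adjusted over the list alone), median 0.33, camera adjusted p = 0.0184, adjusted p = 0.102 with an estimated correlation. Examples were Cxcl2 (216 vs 103, 1.06 ± 0.024) and Cxcl5 (90.7 vs 42.3, 1.08 ± 0.036), both neutrophil chemokine genes. With genes of mean FPKM of at least 5 alone, this list had adjusted p = 0.199. Nuclear genes of oxidative phosphorylation shifted little: 6 of 27 tested members fell and 21 did not pass (6 lower adjusted over the list alone), median -0.10, camera adjusted p = 0.0281, adjusted p = 0.166 with an estimated correlation. Examples were Ndufa1 (50.6 vs 84.7, -0.73 ± 0.070) and Atp5a1 (131 vs 154, -0.24 ± 0.032). That call also ended without a mean-variance trend (adjusted p = 0.0588), with mean FPKM of at least 5 (0.064) and without PPK sham replicate B (0.0523). Of the mitochondrially encoded genes, 11 of 13 tested members fell and 2 did not pass (11 lower adjusted over the list alone), median -0.25, camera adjusted p = 1.60e-06, adjusted p = 0.166 with an estimated correlation. An example was mt-Cytb (3778 vs 5125, -0.44 ± 0.021). Under quantile normalization this list had adjusted p = 0.105.

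In PP sham, 8 of the 13 tested macrophage markers and 4 of the 13 tested fibroblast markers were already at 1 FPKM or more, and none of either list belongs to another list.

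Lineage lists did not pass in sham mice. Beside Tgm4 and Pbsn, the secretory gene Msmb (10.7 vs 68.3, -2.56 ± 0.062), which encodes a secreted microseminoprotein, fell. In the luminal list, 6 of 16 tested members rose, 4 fell and 6 did not pass (6 higher and 5 lower adjusted over the list alone), median -0.09, camera adjusted p = 0.743. In it, Cd24a (392 vs 546, -0.48 ± 0.023) and Prom1 (150.3 vs 68.2, 1.14 ± 0.12) passed. Basal genes were mixed, as 7 of 17 tested members rose, 5 fell and 5 did not pass (8 higher and 5 lower adjusted over the list alone), median 0.24, camera adjusted p = 0.102. Examples were Krt15 (1273 vs 809, 0.65 ± 0.022) and Itga6 (17.4 vs 26.2, -0.57 ± 0.046), the gene of the sorted antigen CD49f. In the squamous list, 4 of 22 tested members rose, 10 fell and 8 did not pass (4 higher and 10 lower adjusted over the list alone), median -0.06, camera adjusted p = 0.0849. Examples were Sprr1a (306 vs 535, -0.80 ± 0.035) and Ivl (11.9 vs 23.8, -0.94 ± 0.058), both genes of the cornified envelope. The castration-tolerant progenitor list was split: 7 of 16 tested members rose, 7 fell and 2 did not pass (7 higher and 7 lower adjusted over the list alone), median 0.09, camera adjusted p = 0.966. Its mean was negative while its median was positive, and Psca (23.2 vs 133, -2.47 ± 0.085) fell. Of 8 tested seminal vesicle genes 5 rose and 3 fell (5 and 3 adjusted over the list alone, camera adjusted p = 0.0866), with Svs2 (238 vs 809, -1.76 ± 0.043) lower and Svs4 (75.3 vs 13, 2.44 ± 0.077) higher. The p53 list (8 rose and 5 fell of 25, 10 and 5 adjusted over the list alone, camera adjusted p = 0.199) held Eda2r (5.86 vs 2.30, 1.06 ± 0.083) and Btg2 (561 vs 807, -0.52 ± 0.022). The MAPK feedback list (8 rose and 4 fell of 18, 9 and 4 adjusted over the list alone, camera adjusted p = 0.0669) held Dusp4 (112 vs 68.5, 0.70 ± 0.029) and Ccnd1 (34.0 vs 19.6, 0.76 ± 0.046). In fatty acid oxidation (0 rose and 3 fell of 18, 0 and 3 adjusted over the list alone, camera adjusted p = 0.142), Hadh (7.51 vs 10.7, -0.45 ± 0.051) fell. Among ribosomal protein genes (5 rose and 5 fell of 40, 5 and 5 adjusted over the list alone, camera adjusted p = 0.633), Rpsa (120.2 vs 90.9, 0.40 ± 0.032) rose and Rpl10 (123 vs 143, -0.22 ± 0.027) fell. Cell cycle genes mostly did not pass (2 rose and 1 fell of 26, 2 and 1 adjusted over the list alone, camera adjusted p = 0.239), nor did the KMT2 complex genes (0 rose and 4 fell of 16, 0 and 3 adjusted over the list alone, camera adjusted p = 0.205).

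The p-values here and below measure only the spread between these libraries, which the labels do not say came from separate animals. Beyond counting noise, this spread was fitted at 1.18 to 1.55% per library. The pairs may thus be technical replicates or pools, and the p-values may not cover differences between animals. Call counts are set beside counts of at least 2-fold changes, which does not mend this.

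The second comparison asked how the epithelium of ADT mice at 6.5 months differed between PPK and PP. Basal and squamous keratin genes were far higher in PPK ADT than in PP ADT, and luminal keratin genes were lower. Krt5 and Krt14, the keratin pair of basal cells, stood at 3243 ± 0.310 against 95.5 ± 1.80 FPKM (5.07 ± 0.051) and at 1523 ± 27.1 against 15.8 ± 2.01 (6.51 ± 0.082). Krt10, a keratin of suprabasal epidermis, stood at 1225 ± 4.71 against 7.76 ± 0.268 FPKM (7.13 ± 0.068, limma adjusted p = 1.15e-08). Krt8 and Krt18, the keratin pair of luminal cells, stood at 290.2 ± 5.73 against 1869.8 ± 19.2 FPKM (-2.68 ± 0.021) and at 492 ± 21 against 1638 ± 5.57 (-1.74 ± 0.035). Interferon response and antigen presentation genes were lower, and cell cycle genes were higher.

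Of 14000 genes tested, 8340 differed, 4552 higher and 3788 lower in PPK ADT, and 2498 of them differed at least 2-fold (1388 higher, 1110 lower). With median-of-ratios scaling the larger side turned, here, in both comparisons of ADT with age and in the difference of genotype effects, so the balance of directions is not read. Large increases beside the keratins included Ifitm1 (417 vs 6.97, 5.73 ± 0.19), Tmprss11b (304 vs 5.83, 5.48 ± 0.084), Krtdap (123 vs 2.03, 5.36 ± 0.13), a keratinocyte differentiation gene, and Tgm1 (189 vs 3.73, 5.33 ± 0.066), the transglutaminase of the cornified envelope. Sult1c1 (39.3 vs 0.0166, 5.31 ± 0.082), a sulfotransferase gene, and Fscn1 (67.2 vs 0.819, 5.25 ± 0.16), which bundles actin, followed. Large decreases included Pigr (33.0 vs 1070.2, -4.98 ± 0.038), which carries IgA across epithelium, Lypd8 (1.41 vs 67.3, -4.83 ± 0.040), Ifit3 (9.33 vs 251, -4.61 ± 0.042), Ubd (1.97 vs 67.3, -4.52 ± 0.064), a ubiquitin-like gene, and Cxcl15 (9.91 vs 226, -4.38 ± 0.032). The endothelin gene Edn1 (10.9 vs 235, -4.31 ± 0.028), Plat (25.1 vs 481, -4.21 ± 0.027), the tissue plasminogen activator gene, and the chemokine gene Cxcl17 (-4.20 ± 0.053) followed.

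In the basal list, 13 of 17 tested members rose, 2 fell and 2 did not pass (13 higher and 2 lower adjusted over the list alone), median 1.13, camera adjusted p = 4.11e-05. Trp63, the p63 transcription factor gene of basal cells, rose from 0.977 to 23.3 FPKM (3.62 ± 0.081), as did Aqp3 (107 vs 3.56, 4.56 ± 0.078). Itga6, the gene of CD49f, did not pass, at 34.1 against 33.4 FPKM (0.03 ± 0.046, limma adjusted p = 0.61). Squamous keratinization genes were higher: 18 of 22 tested members rose, 2 fell and 2 did not pass (18 higher and 2 lower adjusted over the list alone), median 2.39, camera adjusted p = 4.44e-08. Beside Krt10, examples were Perp (646 vs 66.1, 3.27 ± 0.040), a desmosome gene, and Krt6a (618 vs 144, 2.10 ± 0.027), whereas Gsdmc2 (15.2 vs 175, -3.44 ± 0.028), a gasdermin gene, fell. Among luminal genes, 15 of 16 tested members fell and 1 did not pass (15 lower adjusted over the list alone), median -0.93, camera adjusted p = 7.51e-08. Beside the keratins, Cldn3 (68.3 vs 379, -2.46 ± 0.058), a tight junction gene, and Cd24a (319 vs 512, -0.68 ± 0.023), the gene of another sorted antigen, fell, as did Epcam (313 against 466 FPKM, -0.57 ± 0.026). Markers of stroma moved with the basal genes. In the fibroblast list, 12 of 13 tested members rose and 1 fell (12 higher and 1 lower adjusted over the list alone), median 1.75, camera adjusted p = 7.03e-05. Examples were Fbln1 (15.9 vs 0.650, 3.36 ± 0.11) and Col1a1 (7.30 vs 0.203, 2.79 ± 0.098), both at low levels. In the smooth muscle list, 5 of 6 tested members rose and 1 fell (5 higher and 1 lower adjusted over the list alone), median 1.26, camera adjusted p = 0.0268, adjusted p = 0.148 with an estimated correlation. Examples were Acta2 (7.59 vs 1.33, 1.89 ± 0.11) and Tagln (3.44 vs 0.413, 1.65 ± 0.12). The list of epithelial-mesenchymal transition was higher: 12 of 13 tested members rose and 1 did not pass (12 higher adjusted over the list alone), median 1.71, camera adjusted p = 6.16e-06, adjusted p = 0.0642 with an estimated correlation. Examples were Sparc (11.5 vs 0.788, 2.80 ± 0.087) and Axl (9.55 vs 2.23, 1.71 ± 0.073), a receptor tyrosine kinase gene.

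All tested genes of the interferon response list were lower: 24 of 24 fell (24 lower adjusted over the list alone), median -1.77, camera adjusted p = 4.29e-13. Examples were Rsad2 (12.5 vs 131, -3.29 ± 0.028) and Isg15 (50.9 vs 243, -2.24 ± 0.029), a ubiquitin-like modifier gene. Outside this list the interferon-inducible gene Ifi202b went the other way, at 659.5 in PPK ADT against 171 FPKM in PP ADT. In antigen presentation, 15 of 15 fell (15 lower adjusted over the list alone), median -1.17, camera adjusted p = 1.52e-07. Examples were B2m (1276 vs 3049, -1.26 ± 0.035), the class I light chain gene, H2-K1 (321 vs 634, -0.98 ± 0.023) and Psmb8 (11.6 vs 27.6, -1.19 ± 0.037). Macrophage and monocyte markers were lower beside them: 1 of 13 tested members rose, 11 fell and 1 did not pass (1 higher and 11 lower adjusted over the list alone), median -0.97, camera adjusted p = 0.00151, adjusted p = 0.0613 with an estimated correlation. Examples were Cd14 (15.0 vs 98.8, -2.65 ± 0.079) and Ctss (12.7 vs 29.7, -1.16 ± 0.069). With mean FPKM of at least 5 this list had adjusted p = 0.219. Neutrophil markers were split, with 3 of 4 higher and 1 lower (3 and 1 adjusted over the list alone), as Ltf (786 vs 441, 0.83 ± 0.034) rose and Lcn2 (41.0 vs 232, -2.47 ± 0.067) fell.

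Cell cycle genes were higher: 24 of 26 tested members rose and 2 did not pass (25 higher adjusted over the list alone), median 1.34, camera adjusted p = 4.16e-08. Examples were Mki67 (10.5 vs 2.67, 1.65 ± 0.061), the gene of the proliferation marker Ki-67, Top2a (8.23 vs 1.89, 1.68 ± 0.070) and Rrm2 (14.3 vs 1.43, 2.66 ± 0.084). All ribosomal protein genes tested were higher, since 40 of 40 rose (40 higher adjusted over the list alone), median 1.56, camera adjusted p = 1.21e-19, adjusted p = 0.0642 with an estimated correlation. Examples were Rplp0 (1243 vs 386, 1.68 ± 0.026) and Rpl8 (659 vs 229.6, 1.52 ± 0.027). Of the mitochondrially encoded genes, 13 of 13 rose (13 higher adjusted over the list alone), median 0.32, camera adjusted p = 6.88e-06, adjusted p = 0.173 with an estimated correlation. Examples were mt-Nd1 (3143 vs 2216, 0.50 ± 0.023) and mt-Atp6 (5715 vs 4005, 0.51 ± 0.021). Under quantile normalization the median of this list was 0.00 (adjusted p = 0.586). That scaling gives a gene the same value wherever its rank is the same, so it is no clear test of direction here, and the call held with median-of-ratios scaling. In nuclear oxidative phosphorylation, 22 of 27 tested members rose, 1 fell and 4 did not pass (22 higher and 1 lower adjusted over the list alone), median 0.55, camera adjusted p = 3.15e-05. Examples were Atp5o (64.7 vs 28.1, 1.18 ± 0.037) and Atp5b (217 vs 137, 0.66 ± 0.025). Cholesterol synthesis genes were higher: 18 of 23 tested members rose and 5 did not pass (18 higher adjusted over the list alone), median 0.86, camera adjusted p = 4.11e-05. Examples were Hmgcs1 (44.1 vs 15.6, 1.45 ± 0.076) and Stard4 (8.18 vs 2.02, 1.60 ± 0.074), a sterol carrier gene. Fatty acid synthesis genes were mixed, as 9 of 21 tested members rose, 6 fell and 6 did not pass (10 higher and 7 lower adjusted over the list alone), median 0.15, camera adjusted p = 0.629. Fasn, the fatty acid synthase gene, rose from 14.1 ± 0.270 to 33.8 ± 0.256 FPKM (1.20 ± 0.046), and Elovl6 (7.34 vs 1.12, 1.98 ± 0.093) rose while Me1 (8.19 vs 27.5, -1.63 ± 0.043) fell. In hypoxia and glycolysis, 18 of 22 tested members rose, 1 fell and 3 did not pass (18 higher and 1 lower adjusted over the list alone), median 0.72, camera adjusted p = 4.60e-06. Examples were Ero1l (93.2 vs 19.2, 2.22 ± 0.047) and Ldha (228 vs 102, 1.15 ± 0.029), the lactate dehydrogenase A gene. Immediate early genes were lower beside these groups: 4 of 20 tested members rose, 12 fell and 4 did not pass (4 higher and 12 lower adjusted over the list alone), median -0.21, camera adjusted p = 0.0113, adjusted p = 0.165 with an estimated correlation. Examples were Atf3 (403 vs 922, -1.19 ± 0.022) and Ier3 (99.3 vs 315, -1.66 ± 0.038), whereas Klf4 (122 vs 36.0, 1.74 ± 0.046) rose.

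Wnt and Notch targets did not pass as a list (7 rose and 3 fell of 13, 7 and 3 adjusted over the list alone, camera adjusted p = 0.115), and Jag1 (107 vs 10.8, 3.20 ± 0.060) and Notch1 (68.8 vs 13.1, 2.31 ± 0.050), a Notch ligand and receptor, rose. Neuroendocrine genes did not pass as a list (3 rose and 2 fell of 7, 3 and 2 adjusted over the list alone, camera adjusted p = 0.542), and Ncam1 (4.46 vs 0.126, 2.28 ± 0.13) and Snap25 (10.8 vs 3.67, 1.34 ± 0.099) rose at low levels while Peg10 (0.329 vs 1.71, -1.03 ± 0.092) fell.

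The senescence and SASP list (9 rose and 9 fell of 21, 9 and 9 adjusted over the list alone, camera adjusted p = 0.286) had a positive median and a negative mean, with Cxcl2 (24.2 vs 238, -3.24 ± 0.024) lower and Igfbp3 (74.9 vs 6.21, 3.40 ± 0.054) higher. The MAPK list (7 rose and 6 fell of 18, 7 and 6 adjusted over the list alone, camera adjusted p = 0.687) and fatty acid oxidation (7 rose and 6 fell of 18, 7 and 6 adjusted over the list alone, camera adjusted p = 0.919) also differed in sign between median and mean, with Dusp4 (70.0 vs 187, -1.40 ± 0.029) and Acadl (18.1 vs 61.4, -1.71 ± 0.075) lower. Erythroid genes (4 rose and 1 fell of 5, 4 and 1 adjusted over the list alone, camera adjusted p = 0.212), such as Hba-a1 (5.85 vs 1.20, 1.63 ± 0.12), did not pass as a list. Of 4 tested adipocyte genes 2 rose and 2 fell (2 and 2 adjusted over the list alone), among them Pparg (2.58 vs 12.0, -1.87 ± 0.060) and Lipe (1.93 vs 7.03, -1.46 ± 0.074). Of 4 endothelial genes 2 passed as higher (2 adjusted over the list alone), both under 1 FPKM. For 1 of them, Cdh5, the call ended with a replicate block (limma adjusted p = 0.0533) and with no filter (0.0714).

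**Figure D2:**
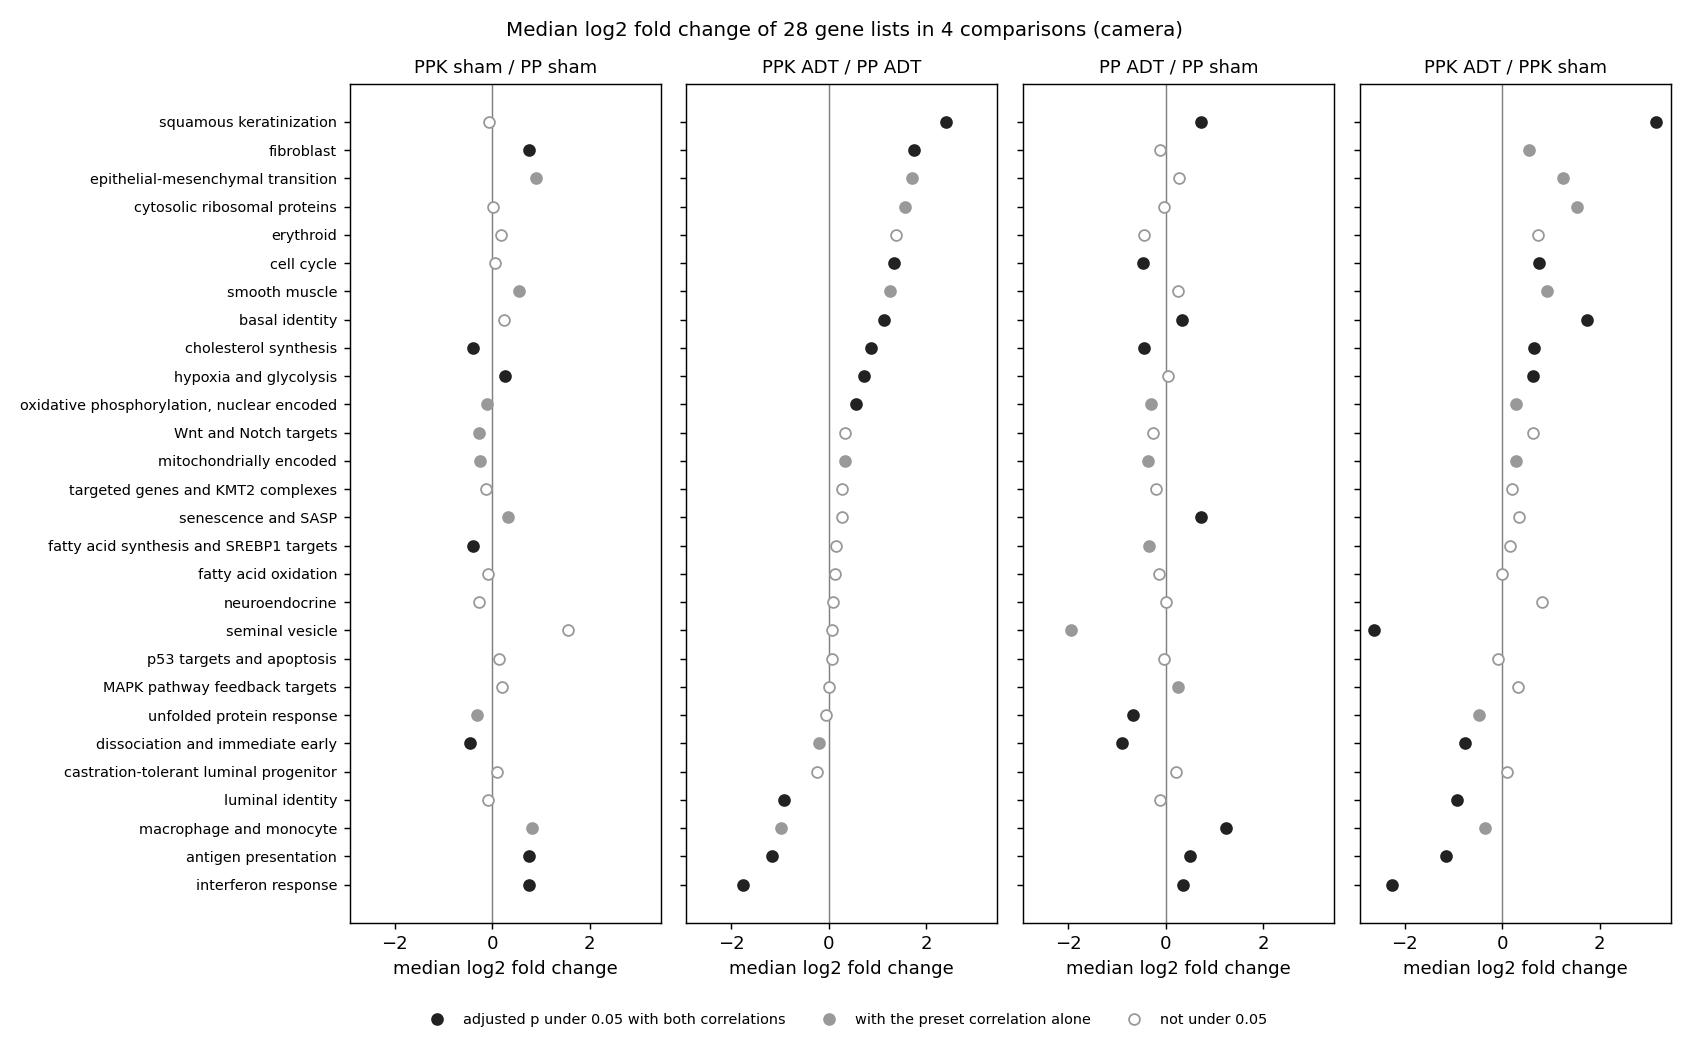
Median log2 fold change (horizontal axis) of 28 lists with at least 5 tested genes (vertical axis) in the 4 pairwise comparisons, where black points had a camera adjusted p under 0.05 with the preset and with the estimated correlation, grey points with the preset one alone, and open points had none. The interferon list lies at 0.76 in PPK sham against PP sham and at -1.77 in PPK ADT against PP ADT, and the squamous list at -0.06 and 2.39.

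The third comparison asked how ADT with age changed the PP epithelium. Several secretory genes were close to 0 or listed at 0 in PP ADT. Svs2, a seminal vesicle secretory protein gene, fell from 809 ± 16.7 to 0.0621 ± 0.0119 FPKM (-9.58 ± 0.043), and Spink1, a trypsin inhibitor gene, from 208 ± 3.53 to 0.318 ± 0.120 (-7.31 ± 0.068). Pbsn, Msmb and Tcaf3 stood at 366 ± 14.9, 68.3 ± 1.70 and 90.7 ± 1.38 FPKM in PP sham and were listed at 0 in both PP ADT libraries. The complement gene C3 rose from 13.9 ± 0.188 to 239.5 ± 0.0855 FPKM (4.01 ± 0.029, limma adjusted p = 7.65e-09), and macrophage markers and antigen presentation genes were higher. The luminal keratin genes Krt8 (1869.8 vs 1263, 0.57 ± 0.021) and Krt18 (1638 vs 984, 0.74 ± 0.035) rose, and Krt19 (1260.2 vs 1701, -0.43 ± 0.022) fell.

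Of 14000 genes tested, 6185 differed, 2667 higher and 3518 lower in PP ADT, and 1214 of them differed at least 2-fold (600 higher, 614 lower). Large increases beside C3 included Ifi202b (171 vs 7.74, 4.30 ± 0.037), an interferon-inducible gene, Cxcl13 (71.2 vs 2.78, 4.26 ± 0.045), the B cell chemokine gene, Tnfrsf11b (60.7 vs 2.62, 4.09 ± 0.071), which encodes osteoprotegerin, Fmo6 (30.2 vs 0.930, 4.01 ± 0.097) and Slpi (42.9 vs 2.11, 3.82 ± 0.078), a secreted protease inhibitor gene. Car12, a carbonic anhydrase gene, rose as well (4.24 ± 0.27), with 97.0 and 52.2 FPKM in the PP ADT pair. Krt6b was listed at 0 in PP sham and at 12.8 ± 0.581 FPKM in PP ADT. Large decreases included Defb50 (0.0713 vs 642, -9.23 ± 0.25), Sbp (0.154 vs 633, -9.10 ± 0.33), the spermine-binding protein gene, and Svs5, at 364 ± 15.7 FPKM in PP sham and listed at 0 in PP ADT.

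Beside Spink1, Tgm4 (0.0777 vs 66.6, -5.97 ± 0.079) fell. Seminal vesicle genes fell with them: 4 of 8 tested members fell and 4 did not pass (4 lower adjusted over the list alone), median -1.94, camera adjusted p = 0.00398, adjusted p = 0.106 with an estimated correlation. In the luminal list, 3 of 16 tested members rose, 9 fell and 4 did not pass (3 higher and 9 lower adjusted over the list alone), median -0.12, camera adjusted p = 0.313, and Cdh1 (706 vs 537, 0.39 ± 0.020), the E-cadherin gene, rose. Basal genes were higher: 10 of 17 tested members rose, 1 fell and 6 did not pass (11 higher and 2 lower adjusted over the list alone), median 0.34, camera adjusted p = 0.000689. Examples were Krt17 (144 vs 29.9, 2.24 ± 0.040) and Lama3 (16.9 vs 8.40, 0.93 ± 0.046), a laminin gene. In the squamous list, 14 of 22 tested members rose, 5 fell and 3 did not pass (16 higher and 5 lower adjusted over the list alone), median 0.72, camera adjusted p = 7.01e-05. Krt13 (34.4 vs 2.38, 3.39 ± 0.091) and Dsc3 (12.6 vs 3.26, 1.68 ± 0.049) rose and Sprr2a3 (15.7 vs 114, -2.79 ± 0.062) fell.

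Interferon response genes were higher, as 15 of 24 tested members rose and 9 did not pass (15 higher adjusted over the list alone), median 0.37, camera adjusted p = 1.34e-07. Examples were Bst2 (136 vs 69.0, 0.97 ± 0.031) and Usp18 (64.6 vs 33.9, 0.91 ± 0.040). In antigen presentation, 13 of 15 tested members rose, 1 fell and 1 did not pass (13 higher and 1 lower adjusted over the list alone), median 0.50, camera adjusted p = 8.29e-06. Examples were the class II genes Cd74 (84.0 vs 9.19, 3.06 ± 0.15) and H2-Ab1 (7.98 vs 1.16, 2.06 ± 0.067). Macrophage and monocyte markers were higher beside them: 12 of 13 tested members rose and 1 fell (12 higher and 1 lower adjusted over the list alone), median 1.23, camera adjusted p = 2.23e-05. Examples were Cd14 (98.8 vs 41.5, 1.23 ± 0.079) and Apoe (22.6 vs 7.86, 1.42 ± 0.11), whereas Mrc1 (2.94 vs 7.51, -1.11 ± 0.072) fell. All 3 tested lymphocyte genes, of 22 listed, and all 4 tested neutrophil genes, of 15 listed, rose (3 and 4 higher adjusted over the list alone), among them Igkc (7.99 vs 0.176, 2.93 ± 0.088) and Lcn2 (232 vs 61.0, 1.91 ± 0.067). The other genes of both lists lay under the FPKM filter. Of those tested, 1 lymphocyte and 2 neutrophil genes reached a mean of 1 FPKM in PP sham. The rest may have been tested only because another group was high, so that all rose is in part built in. In the senescence and SASP list, 12 of 21 tested members rose, 3 fell and 6 did not pass (12 higher and 3 lower adjusted over the list alone), median 0.73, camera adjusted p = 0.000121. Examples were Cxcl5 (536 vs 42.3, 3.63 ± 0.036) and Ccl20 (27.8 vs 6.39, 1.96 ± 0.070), both chemokine genes. The MAPK feedback list was higher: 10 of 18 tested members rose, 4 fell and 4 did not pass (10 higher and 4 lower adjusted over the list alone), median 0.26, camera adjusted p = 0.00349, adjusted p = 0.105 with an estimated correlation. Examples were Dusp4 (187 vs 68.5, 1.43 ± 0.029) and Epha2 (142 vs 53.1, 1.40 ± 0.031), whereas Egr1 (295 vs 504, -0.77 ± 0.030) fell.

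Cell cycle genes were lower, since 19 of 26 tested members fell and 7 did not pass (19 lower adjusted over the list alone), median -0.46, camera adjusted p = 0.000261. Examples were Plk1 (0.836 vs 8.0, -2.29 ± 0.10) and Mki67 (2.67 vs 4.63, -0.62 ± 0.061). Cholesterol synthesis genes were lower too: 1 of 23 tested members rose, 14 fell and 8 did not pass (1 higher and 14 lower adjusted over the list alone), median -0.44, camera adjusted p = 0.000859. Examples were Stard4 (2.02 vs 13.1, -2.23 ± 0.074) and Hmgcs1 (15.6 vs 37.8, -1.23 ± 0.076). In fatty acid synthesis, 2 of 21 tested members rose, 11 fell and 8 did not pass (2 higher and 11 lower adjusted over the list alone), median -0.34, camera adjusted p = 0.00573, adjusted p = 0.0711 with an estimated correlation. Examples were Fasn (14.1 vs 23.7, -0.71 ± 0.046) and Insig1 (11 vs 29.7, -1.36 ± 0.092). In the unfolded protein response list, 15 of 20 tested members fell and 5 did not pass (15 lower adjusted over the list alone), median -0.67, camera adjusted p = 1.34e-07. Examples were Hspa5 (231 vs 398, -0.78 ± 0.020) and Creld2 (13.7 vs 35.7, -1.32 ± 0.038). Immediate early and heat shock genes were lower beside it: 1 of 20 tested members rose, 17 fell and 2 did not pass (1 higher and 19 lower adjusted over the list alone), median -0.90, camera adjusted p = 9.44e-10. Examples were Hspa1a (158 vs 398, -1.33 ± 0.026) and Nr4a1 (116 vs 343, -1.56 ± 0.039). In nuclear oxidative phosphorylation, 1 of 27 tested members rose, 18 fell and 8 did not pass (1 higher and 19 lower adjusted over the list alone), median -0.29, camera adjusted p = 0.000717, adjusted p = 0.0651 with an estimated correlation. Examples were Ndufa1 (29.6 vs 84.7, -1.48 ± 0.070) and Uqcrfs1 (39.2 vs 56.2, -0.51 ± 0.030). All mitochondrially encoded genes tested were lower: 13 of 13 fell (13 lower adjusted over the list alone), median -0.36, camera adjusted p = 1.34e-07, adjusted p = 0.118 with an estimated correlation. An example was mt-Co1 (8107 vs 11423, -0.50 ± 0.017). Under quantile normalization the list had adjusted p = 0.418 and mt-Co1 a log2 fold change of 0.00. Fibroblast markers did not pass as a list (1 rose and 5 fell of 13, 1 and 5 adjusted over the list alone, camera adjusted p = 0.668) and had a negative median beside a positive mean.

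The fourth comparison asked how ADT with age changed the PPK epithelium. Squamous and basal genes rose, and genes of the luminal and interferon lists fell. Krt5 rose from 21.5 ± 0.713 to 3243 ± 0.310 FPKM (7.17 ± 0.051) and Krt10 from 0.942 ± 0.0178 to 1225 ± 4.71 (9.30 ± 0.068, limma adjusted p = 2.42e-09). Klk1 fell from 189 ± 3.68 to 0.762 ± 0.0301 FPKM (-6.76 ± 0.084), and Fcgbp, which encodes a mucus protein, from 157 ± 0.863 to 0.456 ± 0.0690 (-6.76 ± 0.047).

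Of 14000 genes tested, 8765 differed, 4473 higher and 4292 lower in PPK ADT, and 2761 of them differed at least 2-fold (1408 higher, 1353 lower). Beside Krt5 and Krt10, large increases included Calml3 (221 vs 0.178, 7.57 ± 0.15), a calmodulin-like gene of keratinocytes, Tmprss11b (304 vs 0.660, 7.53 ± 0.084), Ifitm1 (417 vs 2.01, 7.13 ± 0.19) and Krt13 (357 vs 3.20, 6.42 ± 0.091), a keratin of stratified mucosa. Krt6b was listed at 0 in PPK sham and at 118 ± 2.38 FPKM in PPK ADT. Large decreases in PPK included Svs2 (0.160 vs 238, -7.69 ± 0.043), Svs5 (0.170 vs 199, -7.43 ± 0.13) and Sbp (0.231 vs 786, -9.21 ± 0.33), whose PPK sham pair read 1082 and 489 FPKM. Spink1 (113 ± 2.38 FPKM) and Tff3, a trefoil factor gene (84.4 ± 0.456 FPKM), were listed at 0 in both PPK ADT libraries.

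In the squamous list, 20 of 22 tested members rose and 2 fell (20 higher and 2 lower adjusted over the list alone), median 3.16, camera adjusted p = 2.13e-09. Sfn, the stratifin gene, rose (1489 vs 346, 2.10 ± 0.021) and Gsdmc2 (15.2 vs 129, -3.00 ± 0.028) fell. Basal genes were higher: 15 of 17 tested members rose and 2 fell (15 higher and 2 lower adjusted over the list alone), median 1.74, camera adjusted p = 1.23e-05. Examples were Krt14 (1523 vs 22.0, 6.05 ± 0.082) and Aqp3 (107 vs 0.905, 5.82 ± 0.078). In the luminal list, 15 of 16 tested members fell and 1 did not pass (15 lower adjusted over the list alone), median -0.93, camera adjusted p = 9.66e-08. Examples were Krt8 (290.2 vs 1341, -2.21 ± 0.021) and Epcam (313 vs 560.3, -0.84 ± 0.026), the gene of a sorted antigen. In the seminal vesicle list, 8 of 8 fell (8 lower adjusted over the list alone), median -2.63, camera adjusted p = 1.29e-05. In the interferon list, 24 of 24 fell (24 lower adjusted over the list alone), median -2.26, camera adjusted p = 1.93e-12. Examples were Rsad2 (12.5 vs 259, -4.26 ± 0.028) and Ifit3 (9.33 vs 301, -4.87 ± 0.042). The interferon-inducible gene Ifi202b, outside the list, stood higher, at 659.5 in PPK ADT against 20.7 FPKM in PPK sham. In antigen presentation, 1 of 15 tested members rose, 11 fell and 3 did not pass (1 higher and 11 lower adjusted over the list alone), median -1.15, camera adjusted p = 0.000144. Examples were B2m (1276 vs 4647, -1.86 ± 0.035) and H2-D1 (491 vs 1543, -1.65 ± 0.027). Macrophage markers were weakly lower beside them: 1 of 13 tested members rose, 5 fell and 7 did not pass (1 higher and 5 lower adjusted over the list alone), median -0.35, camera adjusted p = 0.049, adjusted p = 0.138 with an estimated correlation. Among them Cd14 (15.0 vs 90.5, -2.52 ± 0.079) fell. This call also ended with either PP sham library left out (adjusted p = 0.0555) or PPK sham replicate B left out (0.0601), and in 4 other settings. The 3 tested lymphocyte genes, of 22 listed, rose (3 adjusted over the list alone), among them Igkc (6.58 vs 0.227, 2.63 ± 0.088). Genes as low in sham mice as Igkc may have been tested only because an ADT group was high. The 4 tested endothelial genes, of 13 listed, fell (4 adjusted over the list alone), among them Pecam1 (0.373 vs 1.28, -0.73 ± 0.092).

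Cell cycle genes were higher: 22 of 26 tested members rose, 1 fell and 3 did not pass (22 higher and 1 lower adjusted over the list alone), median 0.76, camera adjusted p = 2.94e-05. Examples were Rrm2 (14.3 vs 3.39, 1.80 ± 0.084) and Top2a (8.23 vs 3.70, 0.97 ± 0.070). Of the ribosomal protein genes, 40 of 40 rose (40 higher adjusted over the list alone), median 1.53, camera adjusted p = 2.41e-19, adjusted p = 0.0644 with an estimated correlation. An example was Rps6 (458 vs 142, 1.68 ± 0.032). In cholesterol synthesis, 18 of 23 tested members rose, 1 fell and 4 did not pass (18 higher and 1 lower adjusted over the list alone), median 0.65, camera adjusted p = 5.52e-05. Examples were Hmgcs1 (44.1 vs 20.3, 1.08 ± 0.076) and Sc5d (20.3 vs 12.7, 0.64 ± 0.044). Fasn rose (33.8 vs 16.7, 0.98 ± 0.046), and fatty acid synthesis did not pass as a list (9 rose and 7 fell of 21, 10 and 7 adjusted over the list alone, camera adjusted p = 0.483). Hypoxia and glycolysis genes were higher: 16 of 22 tested members rose, 2 fell and 4 did not pass (16 higher and 2 lower adjusted over the list alone), median 0.63, camera adjusted p = 6.86e-05. Examples were Ndrg1 (104 vs 24.6, 2.04 ± 0.041) and Hk2 (144 vs 66.8, 1.09 ± 0.026), a hexokinase gene. In the fibroblast list, 12 of 13 tested members rose and 1 fell (12 higher and 1 lower adjusted over the list alone), median 0.55, camera adjusted p = 0.0016, adjusted p = 0.0591 with an estimated correlation. Examples were Dcn (8.70 vs 3.51, 1.1 ± 0.074) and Postn (4.01 vs 0.480, 1.76 ± 0.088). In smooth muscle, 5 of 6 tested members rose and 1 did not pass (5 higher adjusted over the list alone), median 0.93, camera adjusted p = 0.0127, adjusted p = 0.105 with an estimated correlation, and Smtn (29.1 vs 8.52, 1.66 ± 0.053) rose. In epithelial-mesenchymal transition, 12 of 13 tested members rose and 1 did not pass (12 higher adjusted over the list alone), median 1.24, camera adjusted p = 5.52e-05, adjusted p = 0.0742 with an estimated correlation. Snai2, which encodes a repressor of E-cadherin, rose (3.17 vs 0.307, 1.67 ± 0.10). In nuclear oxidative phosphorylation, 18 of 27 tested members rose, 1 fell and 8 did not pass (18 higher and 1 lower adjusted over the list alone), median 0.28, camera adjusted p = 0.00106, adjusted p = 0.0644 with an estimated correlation. Of the mitochondrially encoded genes, 10 of 13 tested members rose, 1 fell and 2 did not pass (10 higher and 1 lower adjusted over the list alone), median 0.29, camera adjusted p = 0.00603, adjusted p = 0.362 with an estimated correlation. Examples were Atp5b (217 vs 145, 0.58 ± 0.025) and mt-Nd3 (320.2 vs 200.2, 0.68 ± 0.032). Under quantile normalization the median of the mitochondrially encoded list was 0.00 (adjusted p = 0.566). The unfolded protein response was lower: 2 of 20 tested members rose, 15 fell and 3 did not pass (2 higher and 16 lower adjusted over the list alone), median -0.48, camera adjusted p = 0.000334, adjusted p = 0.105 with an estimated correlation. Immediate early genes moved with it, as 2 of 20 tested members rose, 16 fell and 2 did not pass (2 higher and 16 lower adjusted over the list alone), median -0.77, camera adjusted p = 5.78e-06. Examples were Calr (254 vs 455, -0.84 ± 0.026) and Hspb1 (396 vs 726, -0.87 ± 0.020).

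Median, mean and test also differed in sign for the progenitor list (8 rose and 7 fell of 16, 9 and 7 adjusted over the list alone, camera adjusted p = 0.809), the p53 list (10 rose and 10 fell of 25, 10 and 10 adjusted over the list alone, camera adjusted p = 0.983) and the senescence and SASP list (10 rose and 9 fell of 21, 10 and 9 adjusted over the list alone, camera adjusted p = 0.983).

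The fifth comparison asked whether the difference between genotypes itself differed between ADT and sham mice. A positive value means that PPK against PP was higher in ADT than in sham mice, and here rose and fell give the sign of that value. The genotype difference of interferon genes turned from higher to lower: 24 of 24 fell (24 lower adjusted over the list alone), median -2.78, camera adjusted p = 4.97e-16. Examples were Rsad2 (-4.64 ± 0.040) and Isg15 (-3.35 ± 0.042). Antigen presentation went the same way, as 15 of 15 fell (15 lower adjusted over the list alone), median -1.90, camera adjusted p = 1.60e-09. Examples were H2-D1 (-1.98 ± 0.039) and B2m (-1.38 ± 0.049). The difference was more positive in ADT mice for squamous genes: 19 of 22 tested members rose, 1 fell and 2 did not pass (19 higher and 1 lower adjusted over the list alone), median 2.31, camera adjusted p = 1.60e-09. Examples beside Krt10 were Perp (3.80 ± 0.057) and Krt6a (2.40 ± 0.038). The same held for cholesterol synthesis: 20 of 23 tested members rose and 3 did not pass (21 higher adjusted over the list alone), median 1.28, camera adjusted p = 6.85e-07. Examples were Hmgcs1 (2.32 ± 0.11) and Stard4 (2.82 ± 0.10). Krt5 (5.46 ± 0.072), Aqp3 (5.49 ± 0.11) and Krt14 (5.28 ± 0.12) rose in the basal list: 13 of 17 tested members rose, 3 fell and 1 did not pass (13 higher and 3 lower adjusted over the list alone), median 0.76, camera adjusted p = 0.00114, adjusted p = 0.0621 with an estimated correlation. Luminal genes were more negative in ADT mice: 1 of 16 tested members rose, 13 fell and 2 did not pass (1 higher and 14 lower adjusted over the list alone), median -0.78, camera adjusted p = 2.28e-06. Examples were Krt8 (-2.77 ± 0.030) and Cldn3 (-2.83 ± 0.082).

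Of 14000 genes tested, 7395 passed, 4198 positive and 3197 negative, and 2944 of them had a log2 difference of at least 1 in size (1578 positive, 1366 negative). With median-of-ratios scaling 3625 genes changed were positive and 3632 negative for this interaction of Kmt2c loss and ADT, so the excess of positive values is not held. The largest positive values belonged to Rnase1 (7.68 ± 0.079), Krt10 (7.23 ± 0.097), Defb1 (5.95 ± 0.23), Fabp5 (5.64 ± 0.10), a fatty acid binding protein gene, and Tmprss11b (5.60 ± 0.12). The largest negative values belonged to Lypd8 (-6.42 ± 0.057), Ifit3 (-5.65 ± 0.059), mt-Tg (-5.61 ± 0.69), Clca3a2 (-5.50 ± 0.069), Pigr (-5.46 ± 0.054) and Cp (-5.45 ± 0.081), the ceruloplasmin gene. Cell cycle genes were more positive in ADT mice: 25 of 26 tested members rose and 1 did not pass (25 higher adjusted over the list alone), median 1.31, camera adjusted p = 3.12e-07. Examples were Rrm2 (2.26 ± 0.12) and Mki67 (1.35 ± 0.087). So were ribosomal protein genes, as 40 of 40 rose (40 higher adjusted over the list alone), median 1.56, camera adjusted p = 1.26e-19, adjusted p = 0.0836 with an estimated correlation. Examples were Rps6 (1.76 ± 0.045) and Rplp0 (1.60 ± 0.037). In nuclear oxidative phosphorylation, 22 of 27 tested members rose, 1 fell and 4 did not pass (23 higher and 1 lower adjusted over the list alone), median 0.63, camera adjusted p = 1.32e-05. Of the mitochondrially encoded genes, 13 of 13 rose (13 higher adjusted over the list alone), median 0.67, camera adjusted p = 5.51e-07, adjusted p = 0.148 with an estimated correlation. Under quantile normalization the median of the mitochondrially encoded list was 0.00 (adjusted p = 0.382). Examples were Atp5o (1.19 ± 0.052) and mt-Nd3 (1.04 ± 0.045). Among Wnt and Notch targets, 9 of 13 tested members rose, 2 fell and 2 did not pass (9 higher and 2 lower adjusted over the list alone), median 1.03, camera adjusted p = 0.0169, adjusted p = 0.118 with an estimated correlation. Examples were Jag1 (3.49 ± 0.085) and Notch1 (2.73 ± 0.071). In epithelial-mesenchymal transition, 11 of 13 tested members rose and 2 did not pass (11 higher adjusted over the list alone), median 0.62, camera adjusted p = 0.0022, adjusted p = 0.148 with an estimated correlation, with Tgfbi (2.77 ± 0.15) among them. In hypoxia and glycolysis, 14 of 22 tested members rose, 6 fell and 2 did not pass (14 higher and 6 lower adjusted over the list alone), median 0.49, camera adjusted p = 0.0355, adjusted p = 0.135 with an estimated correlation. An example was Hk2 (0.87 ± 0.037). The call also ended without PPK sham replicate B (adjusted p = 0.0669), without a trend (0.0627) and under quantile normalization (0.113). Macrophage markers were more negative beside the interferon genes: 13 of 13 fell (13 lower adjusted over the list alone), median -1.61, camera adjusted p = 1.62e-06, with Cd14 (-3.76 ± 0.11) among them. Fibroblast markers were more positive: 12 of 13 tested members rose and 1 fell (12 higher and 1 lower adjusted over the list alone), median 0.97, camera adjusted p = 0.00638, adjusted p = 0.0904 with an estimated correlation, with Fbln1 (2.42 ± 0.16) among them. Fatty acid synthesis genes did not pass as a list (14 rose and 5 fell of 21, 14 and 5 adjusted over the list alone, camera adjusted p = 0.0626), with Fasn (1.68 ± 0.065) and Acly (1.47 ± 0.058) positive and Me1 (-1.04 ± 0.061) negative. Among secretory genes, Tgm4 (5.13 ± 0.11) was positive and Klk1 (-5.44 ± 0.12) negative, and both were under 2 FPKM in the ADT groups, so these values largely restate the sham difference. Median, mean and test differed in sign for fatty acid oxidation (8 rose and 2 fell of 18, 8 and 3 adjusted over the list alone, camera adjusted p = 0.609) and the p53 list (12 rose and 7 fell of 25, 12 and 7 adjusted over the list alone, camera adjusted p = 0.702). Kmt2c did not pass (0.10 ± 0.094, limma adjusted p = 0.415).

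Across the 14000 genes, which are not independent replicates, the genotype effect in sham mice and that in ADT mice had a Pearson correlation of -0.008 and a Spearman correlation of -0.013. They share no library. Of the genes called in both, 638 were higher in both (624 for independent lists), 823 lower in both (563) and 1565 opposite (1196). The ADT effects in PP and in PPK had a Pearson correlation of 0.359 and a Spearman correlation of 0.239. Here 1226 genes were higher in both (852 for independent lists), 1796 lower in both (1079) and 1560 opposite (1942). Genes lower in both genotypes after ADT included Spink1 and Svs2, and genes that went opposite ways included Krt8, Krt18, Rsad2 and Fasn.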

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

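The tests of scaling, of other cell types, of the sort and of secretory genes were chosen only after the results were seen, and the test of length and GC content was chosen before.

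The genotype effect differed between ADT and sham mice in 7395 of 14000 genes by the test of that difference itself (limma, and camera for lists), and each list and gene here is given because it passed that test. A positive log2 value means PPK against PP was higher in ADT than in sham mice. List medians were -2.78 for interferon response, -1.90 for antigen presentation, -1.61 for macrophage and monocyte and -0.78 for luminal identity. They were 2.31 for squamous keratinization, 1.56 for ribosomal proteins, 1.31 for cell cycle, 1.28 for cholesterol synthesis and 1.03 for Wnt and Notch targets. With an estimated correlation the calls of ribosomal proteins (adjusted p = 0.0836) and of Wnt and Notch targets (adjusted p = 0.118) ended. Smaller positive medians were 0.97 for fibroblast, 0.76 for basal identity, 0.67 for mitochondrially encoded genes, 0.63 for nuclear oxidative phosphorylation, 0.62 for epithelial-mesenchymal transition and 0.49 for hypoxia and glycolysis. Of these only nuclear oxidative phosphorylation passed with an estimated correlation, where the adjusted p was 0.0904 for fibroblast, 0.0621 for basal identity, 0.148 for mitochondrially encoded genes and for epithelial-mesenchymal transition, and 0.135 for hypoxia. The mitochondrially encoded median was 0.00 under quantile normalization. Among genes, Rnase1 was at 7.68, Krt10 at 7.23, Defb1 at 5.95, Fabp5 at 5.64 and Tmprss11b at 5.60. Tcaf3, listed at 0 in all 4 ADT libraries, had a fitted value of 5.58 that rests on the sham libraries. Lypd8 was at -6.42, Ifit3 at -5.65, mt-Tg at -5.61, Clca3a2 at -5.50, Pigr at -5.46 and Cp at -5.45.

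Basal and squamous genes were higher and luminal genes lower in PPK ADT than in PP ADT. A lower share of luminal cells that raises the markers of every other cell type alike would raise both the macrophage and the fibroblast list. The macrophage median was -0.97 (11 of 13 lower by limma), beside a fibroblast median of 1.75 (12 of 13 higher). The macrophage list call was lost with an estimated correlation (camera adjusted p = 0.0613) and with mean FPKM at least 5 (0.219). Only 4 of 13 fibroblast members reached 1 FPKM in PP sham, so some may have been tested only because another group was high. The macrophage markers thus did not rise with the fibroblast markers. Whether these transcripts came from macrophages or from the sorted epithelium is not known. These medians therefore do not decide on an equal rise of all other cell types. They leave open a lower luminal share with a gain of basal cells. The scaling of the deposited values is argued against, since the smaller rescaled basal median was 1.07, near the 1.13 without rescaling. For basal cells that passed the CD49f-low sort the change of Itga6, the gene of CD49f, was 0.03 ± 0.046. All cells were sorted for low CD49f, so basal cells that passed need not raise Itga6. Its value thus cannot decide on this source. Bulk values cannot part added basal cells from changed luminal cells, so this source and a change of the cells with loss of Kmt2c, which was not tested, both stay open.

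All 40 tested ribosomal protein genes were higher in PPK ADT than in PP ADT. GC content and, in part, transcript length are argued against: 200 other genes matched on length, GC content and level had a median of 0.057 (quartiles -0.67 and 0.65) beside 1.56 for the ribosomal genes. The match was close for GC (51.2 against 51.9%) and less so for length (1733 against 1124 bases). Length was that of the longest annotated transcript, so an effect on short transcripts is not excluded. Scaling is argued against by the smaller rescaled median of 1.28. Pseudogene reads and a real change in the cells remain open and untested, and with an estimated correlation the list had adjusted p = 0.0642.

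Secretory genes differed in both directions between PPK sham and PP sham. Seminal vesicle tissue in the dissection of 1 genotype is argued against as the whole cause by 3 seminal vesicle genes lower beside 5 higher. A different mix of prostate lobes and an effect of Kmt2c on these genes remain open and untested.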

How the results depend on the processing

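The limma treat test and the left-out libraries for the agreement of effects were chosen after the data were seen, and all other alternatives before. In the order Kmt2c loss in sham mice, Kmt2c loss in ADT mice, ADT with age in PP, ADT with age in PPK and interaction, the counts of genes changed were 4000, 8340, 6185, 8765 and 7395. An absolute log2 fold change of at least 1 left 515, 2498, 1214, 2761 and 2944, and limma treat beyond 2-fold left 168, 1436, 584, 1709 and 1453, by construction. With mean FPKM at least 5, fewer genes were tested and all but the first fell more than 1.5 times, to 4918, 3933, 5056 and 4476. With a replicate block the counts were 3755, 8182, 6013, 8626 and 7186. Leaving out 1 library gave 2758 to 3819, 7266 to 8279, 4778 to 6079, 7648 to 8624 and 6529 to 6755, where the lone library of a group is assumed to vary like the other groups. The share of genes changed that were higher moved from 54.6 to 47.3% (Kmt2c loss in ADT mice), 43.1 to 52.8% (ADT with age in PP) and 51.0 to 49.9% (ADT with age in PPK) with median-of-ratios scaling, and the positive and negative counts of the interaction from 4198 and 3197 to 3625 and 3632. That scaling shifted the median of all genes by at most 0.085 in size. The correlation of the genotype effect between sham and ADT was -0.008, 0.052 with pseudocount 0.1, -0.068 with mean FPKM at least 5, and -0.013 to -0.003 with 1 library left out. The cause of its change of sign was not tested, and all values lie near 0. That of the ADT effect between genotypes was 0.359, 0.397, 0.392 and 0.349 to 0.359. Of 145 list results 82 passed. An estimated correlation ended 35 of these, quantile normalization 6 and mean FPKM at least 5 ended 5, fry added 52, and no filter added 14. Some calls ended although the estimate lay under the preset 0.01, as for Wnt and Notch targets (-0.031). The interferon list in sham mice (estimate -0.00797) kept its call, but its camera adjusted p went from 1.64e-14 to 0.0246. A larger correlation between genes thus does not account for every such loss. Both settings differ in more than the correlation, so the very small p-values of the preset one are not read as strength of evidence. Under quantile normalization mitochondrially encoded genes lost or turned their direction. The list median was 0.00 for Kmt2c loss in ADT mice, for ADT with age in PPK and for the interaction. Genes were mt-Atp6 (0.00), mt-Atp8 (0.00), mt-Nd1 (-0.056) and mt-Co3, which turned and passed (-0.13, adjusted p = 0.000411), for Kmt2c loss in ADT mice, mt-Nd4 (0.015) and mt-Co1 (0.00) for ADT with age in PP, mt-Co1 (0.00) for ADT with age in PPK, and mt-Nd1 (-0.041) for the interaction. By construction, quantile normalization gives a gene the same value in libraries where its rank is the same, so it is no clear test for these abundant genes, and median-of-ratios scaling kept all 5 list calls. Over all named genes and alternatives 10966 results kept direction and call, 159 lost the call (with mt-Co1 for ADT with age in PP) and 7 turned or came to 0. Depth is unknown, and calls under about 2-fold were often missed on simulated data.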

Other observations

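The tests of keratin shares and of the shared fall after ADT were chosen only after the results were seen, and the test of genes near Kmt2c was chosen before.

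As a share of all keratin FPKM, Krt8, Krt18, Krt19 and Krt7 of simple epithelium made up 68.5, 66.2 and 70.7% in PP sham, PPK sham and PP ADT, and 11% in PPK ADT (means, n = 2 each, SD at most 0.18). Krt5, Krt14, Krt15 and Krt17 of basal cells made up 15.0, 23.2, 14.0 and 54.5%. In PP sham and PPK sham, Krt5 stood at 28.5 and 21.5 FPKM and Krt14 at 8.78 and 22.0. Krt15 made up most of the basal share in sham mice, so its higher value in PPK sham does not reflect Krt5. Krt1, Krt10, Krt13, Krt4, Krt6a, Krt6b and Krt16 of stratified epithelium made up 11.1, 7.93, 8.3 and 33.5%. In the sham groups Krt10 (1.09 and 0.942 FPKM) and Krt13 (2.38 and 3.20) added little to the stratified share. Summed keratin FPKM was 5838 ± 43.1, 5905 ± 55.7 and 6838 ± 44.1 in the first 3 groups and 11286 ± 115 in PPK ADT (SD).

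A hypothesis was that passenger sequence around the Kmt2c allele on chromosome 5 explains genes with the same genotype effect in sham and in ADT mice. Within 10 Mb of Kmt2c 7 of 141 tested genes (4.96%) were called in the same direction in both comparisons, against 1453 of 13847 elsewhere (10.5%). The odds ratio was 0.446 (two-sided Fisher exact p = 0.0362), the reverse of an excess near Kmt2c. The 141 genes of this window could not account for the 1453 calls elsewhere in any case. The test does not address single genes near Kmt2c.

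Another hypothesis was that genes lower after ADT with age in PP fall in PPK as well. Of 614 genes at least 2-fold lower in PP ADT, 477 (77.7%) were also called lower in PPK and 50 (8.1%) were called higher, beside 30.7% lower among all 14000 genes tested. A shared response to ADT or to age may account for these genes, and the design does not part both.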
